A study of Mus musculus with 2 samples.

How the data were processed

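The study sequenced mRNA from small intestinal epithelial cells of wild-type and of miR-215 knockout mice. The labels give 1 library for each genotype, and both were compared as labelled; whether a library came from 1 animal or several, and the animals' strain, sex and age, are not given in the sources used here. Per the labels' protocols, total RNA was extracted with the RNeasy Mini kit and libraries were made with the TruSeq stranded mRNA kit, which selects polyadenylated RNA and keeps the strand.

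The deposited values are FPKM, fragments per kilobase of transcript relative to the depth of the library, 1 value per gene and library, which the authors made from their reads. The submitters' processing notes name TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cuffnorm 2.2.1 and the build mm10. The role of each tool, the settings, the gene annotation, the use of strand and the scaling between libraries are not given in the sources used here. No header names the unit; FPKM was inferred from the tool named in the notes, from the table layout and from the values. Both libraries list the same 23284 genes by symbol. The summed FPKM were 750631 in the wild-type library and 683884 in the knockout library. Genes whose annotated transcripts are all under 200 nt, whose values rest on few fragments because the length enters the unit, took 2.90% and 6.30% of these sums.

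The files hold no counts, so no count model was used. Depth was read from the steps between low values. Among 602 genes under 0.1 FPKM in both libraries, 246 had the same knockout to wild-type ratio of 0.963, with log2 ratios equal when rounded to 3 decimals, which is the relative worth of 1 fragment, and after division by it 93.7% of the ratios were ratios of whole numbers up to 10 within 0.5%, against 8.33% for random ratios over the same range. From 253 and 261 protein-coding genes with 1 annotated transcript and under 0.3 FPKM, 1 fragment over 1 kb was worth 0.113 FPKM in the wild-type library and 0.109 in the knockout library. Fragment numbers of a gene were estimated with the median length of its annotated transcripts, those linked to RefSeq where there were any, and exact 95% Clopper-Pearson intervals of folds were made from the rounded numbers. These intervals and the floor of 3 fragments cover counting error only, not variation between animals or preparations, and they assume the transcript length. For Mir215 the worth of 1 fragment was interpolated between the lowest values of genes of 108 and 117 nt, and for Mir192 in the same way at its length.

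Coordinates, transcript lengths and 3' UTRs were taken from GENCODE M21 on GRCm38, the assembly of mm10, counted from 1. Of the 23284 symbols, 22822 matched an annotated transcript, directly or through an older symbol in a RefSeq gene table, and 99.0% of the genes kept for comparison did.

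Genes with at least 1 FPKM in at least 1 library were kept, 11504 in all, and the log2 ratio was computed as log2(knockout + 1) minus log2(wild-type + 1). This scale understates the difference of genes with low values, and folds called FPKM folds or given with a counting interval are ratios of the deposited values without the added 1. A gene was counted as apart at 2-fold or more on the log2 scale with the added 1, which is a rule of size and not of significance. For gene lists, the median log2 ratio of the measured members was ranked among 10000 random lists of the same size, drawn from the same 20 bins of mean expression with seed 1; a list of at least 3 measured members stood apart within the outer 2.5% at either end. The 39 lists, with 595 genes, were fixed before the data were examined. They covered the CXCL12 axis, Th17 cells, responses to IL-17 and IL-22, chemokines, cytokines, MHC class II, interferon, the epithelial lineages, proliferation, lymphocytes, myeloid cells, stroma, endothelium, red blood cells, enteric neurons and glia, pancreatic acinar cells, proximal and distal intestine, tight junctions, transporters, cholesterol, fatty acid, drug and retinoid metabolism, the clock, immediate early and heat shock genes, the unfolded protein response, p53 targets, reported miR-192 and miR-215 targets, neighbours of Mir215, sex-linked, housekeeping and mitochondrially encoded genes. Named genes followed a rule fixed at the same time. They were the targeted gene, its neighbours, Cxcl12 with its receptors and the sex-linked genes, then the 10 highest and 10 lowest log2 ratios among genes with at least 5 FPKM in at least 1 library whose symbol is no predicted, clone, small RNA or antigen receptor segment name, and from each list up to 4 members of largest log2 ratio in size and the most abundant member; some members that this rule names are not reported here.

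For seed sites, the median log2 ratio of genes with the heptamer in the longest annotated 3' UTR was set against that of genes without it, and the difference was ranked among all other heptamers of the same base composition. The alternatives tried were pseudocounts of 0.1 and 5, a scaling factor that sets the median log2 ratio to 0, both libraries rescaled to a common sum above the deposited ones, equal upper quartiles, no filter on low values, a minimum of 5 FPKM, a mean of at least 1 FPKM, thresholds of 1.5-fold and 3-fold, unmatched random lists, the mean of list members, and for seed sites an octamer, any annotated 3' UTR, a minimum of 5 FPKM and a pseudocount of 0.1. Leaving out genes under 200 nt, removing the trend with transcript length and multiplying the knockout values by 1.1, the ratio of the summed FPKM, so that the sums were equal on the wild-type scale, and leaving the alpha-defensin genes out of the Paneth cell list, were added after the data were seen. That trend was small, with medians from -0.16 in the decile of genes with the shortest transcripts to 0.07 in the decile with the longest.

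The steps were tested on simulated data for this comparison. With fragment numbers drawn for 11212 genes, the size rule found 94 of 100 genes changed 4-fold and 20 of 100 changed 2-fold, and 4 of 11014 unchanged genes. These draws held counting error alone, with no variation between animals or preparations, and left out genes with a median transcript under 200 nt. They therefore give no rate of false calls for the 2 libraries. Of 200 random lists of 15 genes, 9 were called, and of 200 lists shifted by 0.5 on the log2 scale 199 were called. A shift of 0.1 put into the genes with a seed site was found as 0.09. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.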

Results

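Gene expression was measured by mRNA sequencing in small intestinal epithelial cells of a wild-type mouse preparation and of a preparation from mice lacking miR-215, a microRNA abundant in the gut epithelium. There was 1 library per genotype, so no difference below has a replicate check, no p-value across genes is given, and "higher" and "lower" describe the knockout library relative to the wild-type library. Each library listed 23284 genes in FPKM, fragments per kilobase of transcript relative to the depth of the library. The wild-type library had 15445 genes above 0 and 11077 at 1 FPKM or more, and the knockout library had 15700 and 11215. From the steps between low values, a gene with a transcript of 2 kb and a value of 1 FPKM rested on about 17.7 fragments in the wild-type library and 18.3 in the knockout library, a counting CV of 23.7% and 23.4%. The 10 highest genes took 14.0% of the summed FPKM in the wild-type library and 15.8% in the knockout library.

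The targeted gene was read first. Mir215 lies on chromosome 1 at 185313581 to 185313692 of mm10, on the plus strand, inside an intron of Iars2, which is read from the minus strand and encodes a mitochondrial isoleucyl-tRNA synthetase, and within an exon of the antisense transcript 2010103J01Rik. It was listed at 137 FPKM in the wild-type library and at 0 in the knockout library. Because the gene is 112 nt long, 1 fragment there was worth about 65.6 FPKM, and the wild-type value rested on about 2 fragments. Both libraries were thus at or under the floor of 3 fragments. The loss of the microRNA was not resolved in these libraries, which were made from polyadenylated RNA and not from small RNA. The part of the locus that was deleted is not given in the sources used here. The neighbouring Mir194-1, at 185313319 to 185313385, was listed at 0 in both libraries. Iars2, on the strand opposite to Mir215, was at 13.6 FPKM in the wild-type library and 13.5 in the knockout library. That is a fold of 0.994 with a 95% counting interval of 0.883 to 1.1, and it does not measure a transcript that carries Mir215. Mir192, which has the same seed as miR-215, was listed at 0 in the wild-type library and at 387 FPKM in the knockout library, which over an 89-nt gene was about 1 fragment, under the floor of 3. Xist, expressed from the inactive X chromosome, was at 16.1 FPKM in the wild-type library and 36.4 in the knockout library. The Y-linked genes Uty, Ddx3y and Eif2s3y were at 0 in both, and Kdm5d rested on 1 fragment in the wild-type library and was at 0 in the knockout library.

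The title of the series asks about CXCL12, a chemokine made mainly by stromal cells that attracts lymphocytes through the receptor CXCR4. Cxcl12 (chromosome 6, 117168535 to 117181367) was low in both libraries, at 0.214 FPKM in the wild-type library and 0.779 in the knockout library. The FPKM ratio was 3.65, and the log2 ratio after adding 1 to each value was 0.55. With the transcript of median length, 3132 nt, these values rested on about 6 and 22 fragments, and the 95% counting interval of the fold was 1.39 to 10.6. With the shortest transcript, 1878 nt, the fragments were about 4 and 13 and the interval, 0.967 to 13.2, included no difference. Neither value reached 1 FPKM, so Cxcl12 was outside the set of genes counted below. Cxcr4 was at 4.98 FPKM in the wild-type library and 4.0 in the knockout library (fold interval 0.565 to 1.11). Ackr3, the scavenger receptor of CXCL12, listed under its older symbol Cxcr7, rested on about 2 and 6 fragments. The CXCL12 axis list had 3 measured members, which also include the CXCR4-related chemokine Cxcl14 (0.317 and 3.72 FPKM) and the CXCL12-cleaving peptidase Dpp4 (282 and 233 FPKM). Its median log2 ratio was -0.26, at percentile 16.5 among random lists, while the mean, 0.44, had the opposite sign. The sign of the median depended on the filter, which left out Cxcl12 and Ackr3. Without a filter on low values the median was 0.15 (percentile 83.1). With both libraries raised to a common sum it was 0.30 (percentile 81.4), and with equal sums on the wild-type scale -0.14 (percentile 19.05). The list stood apart under none of these. Markers of fibroblasts and smooth muscle were higher in the same knockout library, with a median log2 ratio of 1.1.

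Among the 11504 genes with at least 1 FPKM in at least 1 library, 154 were at least 2-fold higher and 235 at least 2-fold lower in the knockout library on the log2(FPKM + 1) scale, together 3.38%. A further 87.9% of the genes were within 1.5-fold, the median log2 ratio was -0.05, and the Pearson correlation across genes, which are not independent replicates, was 0.958. The balance of higher to lower depended on the scaling: with the knockout values multiplied by 1 factor to equal sums it was 209 to 185, and with equal upper quartiles 199 to 193. With both libraries raised to a common sum above the deposited ones, which also raised the values against the pseudocount and the filter (12066 genes kept), it was 259 to 216. Rescaling to equal sums moved the median log2 ratio of all genes from -0.05 to 0.07, so the differences below are to be read against those medians. With a pseudocount of 0.1 the counts were 339 higher and 361 lower. Of the genes past 2-fold, 29 higher and 43 lower rested on fewer than 50 estimated fragments in both libraries together, and 23 and 18 had annotated transcripts all under 200 nt.

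**Figure D1:**
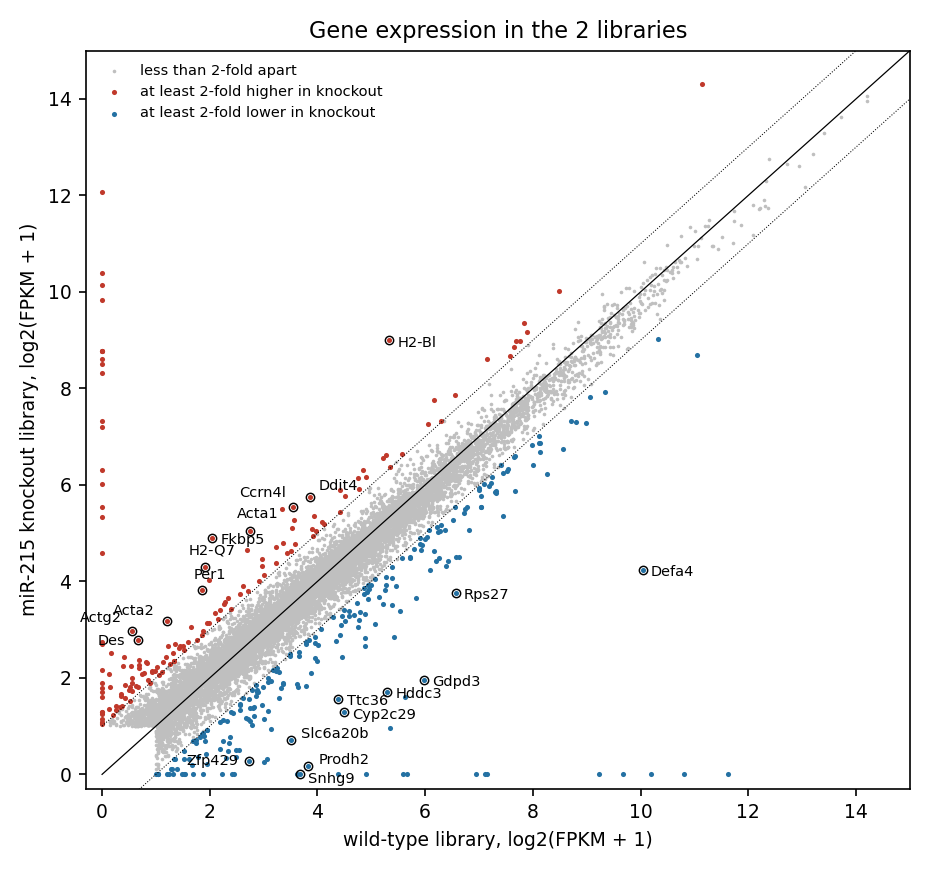
Each point is 1 of the 11504 genes, with log2(FPKM + 1) in the wild-type library on the x axis and in the knockout library on the y axis; the solid line marks equality and the dotted lines 2-fold. The 154 genes at least 2-fold higher are red and the 235 at least 2-fold lower blue, and the 10 named genes of largest difference in each direction are circled.

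The 10 highest log2 ratios are given first, among genes of at least 5 FPKM in at least 1 library and without predicted, clone, small RNA or antigen receptor segment names. H2-Bl, a class I histocompatibility gene annotated as a polymorphic pseudogene (chromosome 17, 36080115 to 36084223), was at 39.2 FPKM in the wild-type library and 509.8 in the knockout library, 13-fold with a counting interval of 11.5 to 14.5. H2-Q7, another class I gene (chromosome 17, 35439155 to 35443773), was 6.75-fold higher (4.66 to 9.69). Fkbp5, a glucocorticoid-inducible co-chaperone of steroid receptors (chromosome 17, 28399094 to 28517527), was at 3.11 and 28.8 FPKM, 9.26-fold (7.43 to 11.4). Ddit4, a stress-induced inhibitor of mTORC1 (chromosome 10, 59949669 to 59951834), was at 13.6 and 53.2 FPKM. The clock gene Per1 (chromosome 11, 69095217 to 69109960) was at 2.61 and 13.2 FPKM, and the rhythmically expressed gene Noct, listed as Ccrn4l (chromosome 3, 51224447 to 51251644), was at 10.7 and 45.5 FPKM. The remaining genes of the 10 were muscle genes. Actg2, the enteric smooth muscle actin (chromosome 6, 83512905 to 83536265), was 14.8-fold higher (6.67 to 51.1), from 0.463 FPKM. Des, the muscle intermediate filament desmin (chromosome 1, 75360329 to 75368579), was 10.1-fold higher (5.83 to 17.5). Acta2, smooth muscle actin (chromosome 19, 34241090 to 34255590), was 6.16-fold higher (3.90 to 9.69), and Acta1, skeletal muscle actin (chromosome 8, 123891769 to 123894751), was 5.62-fold higher (4.34 to 7.26). The actin genes and the class I genes have close paralogs, and how fragments shared between copies were assigned is not given in the sources used here.

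Within the same limits, which leave out Mir215, the lowest log2 ratio was that of Defa4, a Paneth cell alpha-defensin, at 1051 FPKM in the wild-type library and 17.9 in the knockout library; it belongs to a family of near-identical copies and no position was found for it in the annotation used. Gdpd3, a lysophospholipase D (chromosome 7, 126766334 to 126775649), was at 62.0 and 2.87 FPKM, 21.6-fold lower with a counting interval of 15.2 to 32.7. Hddc3 (chromosome 7, 80343104 to 80350547) was at 38.4 and 2.27 FPKM, 16.9-fold lower (12 to 25.6). Prodh2, a mitochondrial hydroxyproline dehydrogenase (chromosome 7, 30493622 to 30513402), was at 13.2 and 0.123 FPKM, about 217 against 2 fragments. Cyp2c29, a cytochrome P450 induced by xenobiotics (chromosome 19, 39269405 to 39330713), was at 21.4 and 1.44 FPKM, 14.9-fold lower (10 to 24.4). Slc6a20b, a relative of the proline transporter Slc6a20a (chromosome 9, 123590800 to 123632565), was 16.1-fold lower (11.7 to 23.4), and Ttc36 (chromosome 9, 44799397 to 44803072) was 10.2-fold lower (6.08 to 18.3). Zfp429, a zinc finger gene (chromosome 13, 67387905 to 67399819), was at 5.62 and 0.217 FPKM, about 103 against 4 fragments. The ribosomal protein gene Rps27 (chromosome 3, 90212522 to 90213651) was at 93.7 and 12.6 FPKM, and the noncoding Snhg9 (chromosome 17, 24719531 to 24719965) was at 11.7 FPKM in the wild-type library and listed at 0 in the knockout library. Cyp2c29, Slc6a20b and Rps27 have close paralogs or processed copies.

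Gene lists fixed before the data were examined were then compared. Of 39 lists, 35 had at least 3 measured members, and 9 stood apart as higher and 5 as lower, where chance would give 1.75 in all. That number is for genes that vary independently, while genes of 1 list can vary together, so it may be too low. A list stood apart when its median was within the outer 2.5% at either end of 10000 random lists matched on mean expression. These percentiles describe these libraries only. Markers of cells other than epithelium are given first. All 12 measured fibroblast and smooth muscle markers had log2 ratios above 0, 6 of them at least 2-fold, with a median of 1.1 above every random list. Besides Des and Acta2, the collagen gene Col6a1 was at 0.599 and 4.17 FPKM and the smooth muscle myosin gene Myh11 at 0.112 and 2.5 FPKM, and the most abundant member, Vim, was at 6.56 and 11 FPKM. Markers of macrophages, dendritic cells and neutrophils had a median of 0.51, above every random list, with 11 of 12 above 0. Among them the complement genes C1qa (4.93 and 12.3 FPKM) and C1qc (6.30 and 12.7 FPKM) differed most, and Tyrobp, the most abundant, was at 30.1 and 22.1 FPKM. T cell and intraepithelial lymphocyte markers had a median of 0.22 (percentile 99.7, 11 of 16 above 0, none 2-fold), although the mean of the members, 0.15, was at percentile 96.7 and did not stand apart. The 5 members below 0 were the CD3 chain genes Cd3d, Cd3e and Cd3g, with Cd160 and Cd7. All but Cd7 stayed below 0 under every scaling tried, so the list did not move as 1 group. Cd8b1 was at 1.70 and 3.11 FPKM, Cd3d at 7.68 and 4.93, and the granzyme gene Gzma, the most abundant, at 250.5 and 261 FPKM. The 5 measured endothelial markers were all above 0 with a median of 0.47 (percentile 93.9), led by Plvap at 0.454 and 3.77 FPKM. B cell and plasma cell markers had a median of -0.17 (percentile 12.5) and a mean of the opposite sign, 0.12, with the immunoglobulin J chain gene, listed as Igj, at 20.3 and 58.6 FPKM. Red blood cell genes were lower, with a median of -2.15 over 3 members (percentile 0.01), among them Hba-a1 at 28.6 and 5.33 FPKM. No enteric neuron or glia marker reached 1 FPKM, and of the pancreatic acinar genes only Clps (75 and 42.5 FPKM) and Cela1 (5.60 and 3.85 FPKM) did. The sex-linked list had 1 measured member, Xist, and the mitochondrially encoded list had 0 of its members among the listed genes.

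**Figure D2:**
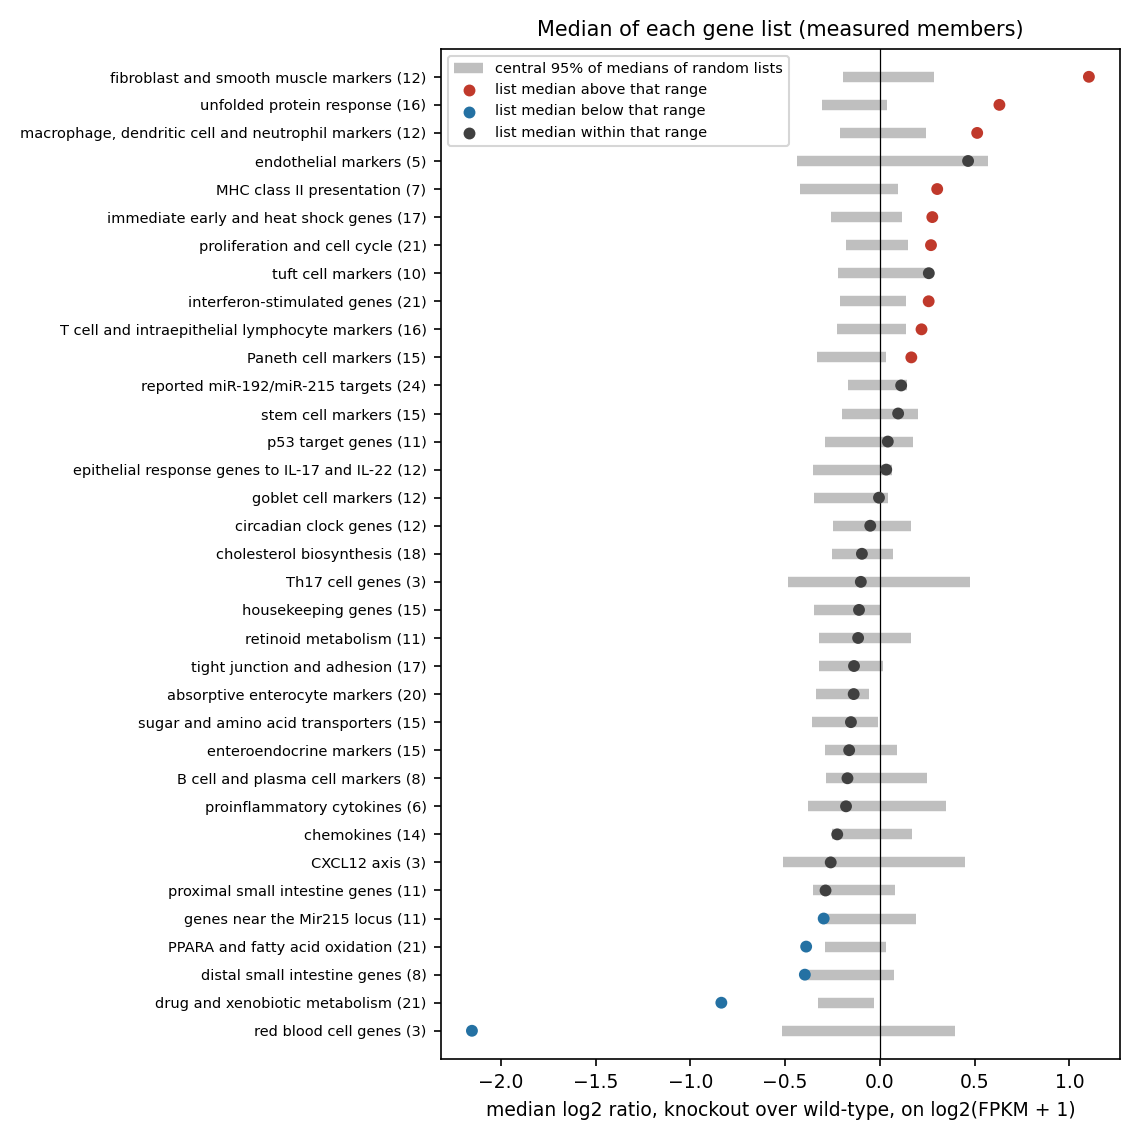
Each dot is the median log2 ratio, knockout over wild-type on log2(FPKM + 1), of the measured members of 1 of the 35 lists, with their number in parentheses; the grey bar is the central 95% of 10000 random lists. The fibroblast and smooth muscle list lies highest at 1.1, and the red blood cell and drug metabolism lists lie lowest at -2.15 and -0.84.

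The series title also names Th17 inflammation. The cytokine genes that define Th17 cells were near or at 0: Il17f and Il22 were listed at 0 in both libraries and Il17a at 0.107 FPKM in the wild-type library and 0 in the knockout library. The 3 measured members of the Th17 list, among them Batf (1.18 and 1.70 FPKM) and Csf2 (1.74 and 1.56), had a median log2 ratio of -0.10, at percentile 30.5. A difference in Th17 transcripts was not detectable at this depth. Epithelial response genes to IL-17 and IL-22 had a median of 0.03 (percentile 95.9) and went both ways: Duox2, an epithelial NADPH oxidase, was at 37.5 and 96.7 FPKM and its maturation factor Duoxa2 at 34.1 and 60.5, while the antimicrobial lectin Reg3a was at 533 and 225 and Saa1 at 88.7 and 49.5. The most abundant member, Reg3b, was at 5343 and 6939 FPKM. This list stood apart as higher once the trend with transcript length was removed (median 0.15, percentile 98.2). Under 11 of the 12 alternatives it did not, and with a minimum of 5 FPKM its median was below 0 (-0.07, percentile 85.05). Chemokines had a median of -0.22 (percentile 4.28), with Ccl20 at 5.88 and 2.34 FPKM, Cxcl13 at 6.24 and 2.59, Cxcl16 at 25.0 and 12.9 and Ccl28 at 11.1 and 19.4, and the most abundant, Ccl25, at 712 and 595. The chemokine list stood apart as lower with a pseudocount of 5 (median -0.19, percentile 1.12) and with a minimum of 5 FPKM (median -0.42, percentile 2.445). Under 10 of the 12 alternatives it did not, and with the length trend removed its median was -0.07, at percentile 23.4. The 6 measured proinflammatory cytokines had a median of -0.18 (percentile 17.3), with Tnf at 1.45 and 0.631 FPKM and Il18 at 106 and 75.5. Of the 6, 3 were above 0, and with a minimum of 5 FPKM the median was 0.13 (percentile 87.5).

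Genes of MHC class II presentation and interferon-stimulated genes were compared next. All 7 genes of MHC class II presentation were above 0, with a median of 0.30 (percentile 99.9), none by 2-fold. Markers of macrophages and dendritic cells, which also express these genes, were higher in the same library, with the dendritic cell integrin gene Itgax at 1.48 and 2.82 FPKM. The invariant chain gene Cd74 was at 1073 FPKM in the wild-type library and 1573 in the knockout library, H2-Aa at 639 and 829.9, and the transactivator Ciita at 6.85 and 8.68. Interferon-stimulated genes had a median of 0.26 (percentile 99.9), with 14 of 21 above 0. The antiviral gene Rsad2 was at 5.13 and 13.9 FPKM and the GTPase gene Iigp1 at 0.413 and 1.66, while the most abundant member, Irf7, was at 149 and 131. The mean of the interferon list, 0.22, was at percentile 96.5 and did not stand apart.

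Among the epithelial lineages, Paneth cell markers stood apart as higher (median 0.17, percentile 99.96, 10 of 15 above 0). The alpha-defensin genes Defa21 (199 and 460.0 FPKM) and Defa22 (189.7 and 409.9) were 2-fold higher, Ang4 was at 131 and 66.5, Mptx1, listed as 1810030J14Rik, was at 6.03 and 1.33, and the most abundant, Defa24, was at 2362 and 2651. The alpha-defensin genes, 7 of the 15 members, are near-identical copies, so their single values are uncertain. Across the family, 5 copies were 2-fold higher and 4 were 2-fold lower, Defa4 among them, and the summed FPKM were 1.12-fold apart. Without its alpha-defensins the list had a median of 0.12 (percentile 97.7), narrowly apart, an alternative chosen after the data were seen. Proliferation and cell cycle genes were above 0 in all 21 members, with a median of 0.27 (percentile 99.98) and none 2-fold apart on the log2(FPKM + 1) scale. The replication licensing genes Mcm3 (5.36 and 11.2 FPKM) and Mcm4 (4.34 and 7.71) and Mki67 (5.60 and 9.45) differed most. Stem cell markers did not stand apart (median 0.10, percentile 83.3), with Lgr5 at 1.91 and 1.01 FPKM and Olfm4 at 149 and 202. Absorptive enterocyte markers had a median of -0.14 (percentile 74.1), with the apolipoprotein gene Apoc3 at 4374 and 2314 FPKM and Apoa1 at 18904 and 17185. Goblet cell markers had a median of -0.00 (percentile 93.4) and a mean of 0.01 (percentile 89.4), with Guca2a at 1309 and 689 FPKM and Zg16 at 9440 and 7443. Enteroendocrine markers had a median of -0.16 (percentile 25.3), with 2 of 15 members 2-fold lower, the hormone genes Sst (104 and 41.7 FPKM) and Ghrl (54.4 and 24.5). Tuft cell markers had a median of 0.26 (percentile 97.2), just short of standing apart, and did so under 4 of the alternatives tried, with Alox5ap at 8.57 and 5.51 FPKM and Ptgs1 at 1.97 and 3.31. Under 8 of the 12 alternatives they did not. With a minimum of 5 FPKM their median was 0.04 (percentile 64.3), and the mean of members was 0.11 (percentile 77.8). Genes of tight junctions and adhesion had a median of -0.14 (percentile 53.9), with Cldn4 at 181 and 120 FPKM. Housekeeping genes had a median of -0.11 (percentile 71.7), which became 0.02 with values rescaled to equal sums, with B2m at 4989 and 3824 FPKM.

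All 21 measured genes of drug and xenobiotic metabolism had log2 ratios below 0 under every scaling tried, 6 of them at least 2-fold, and their median of -0.84 was below every random list. Besides Cyp2c29, the P450 genes Cyp2c66 (94.6 and 21.6 FPKM), Cyp2c65 (279 and 102) and Cyp3a11 (1284 and 517) differed most, and the carboxylesterase gene Ces2e, the most abundant, was at 1292 and 847. The list of PPARA targets and fatty acid oxidation had a median of -0.39 (percentile 0.17, 16 of 21 below 0), with Cyp4a10 at 5.57 and 1.21 FPKM, Acaa1b at 33.8 and 16.8 and Acot1 at 3.57 and 1.54. Angptl4, a lipoprotein lipase inhibitor on the same list, went the other way at 65.1 and 152 FPKM, and the mean of the list, -0.28, was at percentile 7.26 and did not stand apart. Distal small intestine genes were lower (median -0.40, percentile 2.18, 7 of 8 below 0; percentile 2.95 with the trend with transcript length removed), with the nuclear receptor gene Nr0b2 at 14.9 and 4.13 FPKM, Fabp6 at 4354 and 3554 and Fgf15 at 20.9 in the knockout library against 13.7. Proximal small intestine genes were below 0 in all 11 members, 8 with values rescaled to equal sums, and did not stand apart (median -0.29, percentile 7.84), with Adh6a at 862 and 451 FPKM and Apoa4 at 13536 and 12581. Sugar and amino acid transporters had a median of -0.15 (percentile 54.5), with 2 of 15 members 2-fold lower, the proline transporter gene Slc6a20a (304 and 74.1 FPKM) and Slc5a4a (63.3 and 28.2). Retinoid metabolism had a median of -0.11 (percentile 39.4), with the retinaldehyde dehydrogenase gene Aldh1a1 at 419 and 159 FPKM, Rdh7 at 276 and 127 and Aldh1a3 at 0.193 and 1.67. Cholesterol biosynthesis had a median of -0.09 (percentile 44.7), with Hmgcs1 at 60.7 and 43.2 FPKM.

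**Figure D3:**
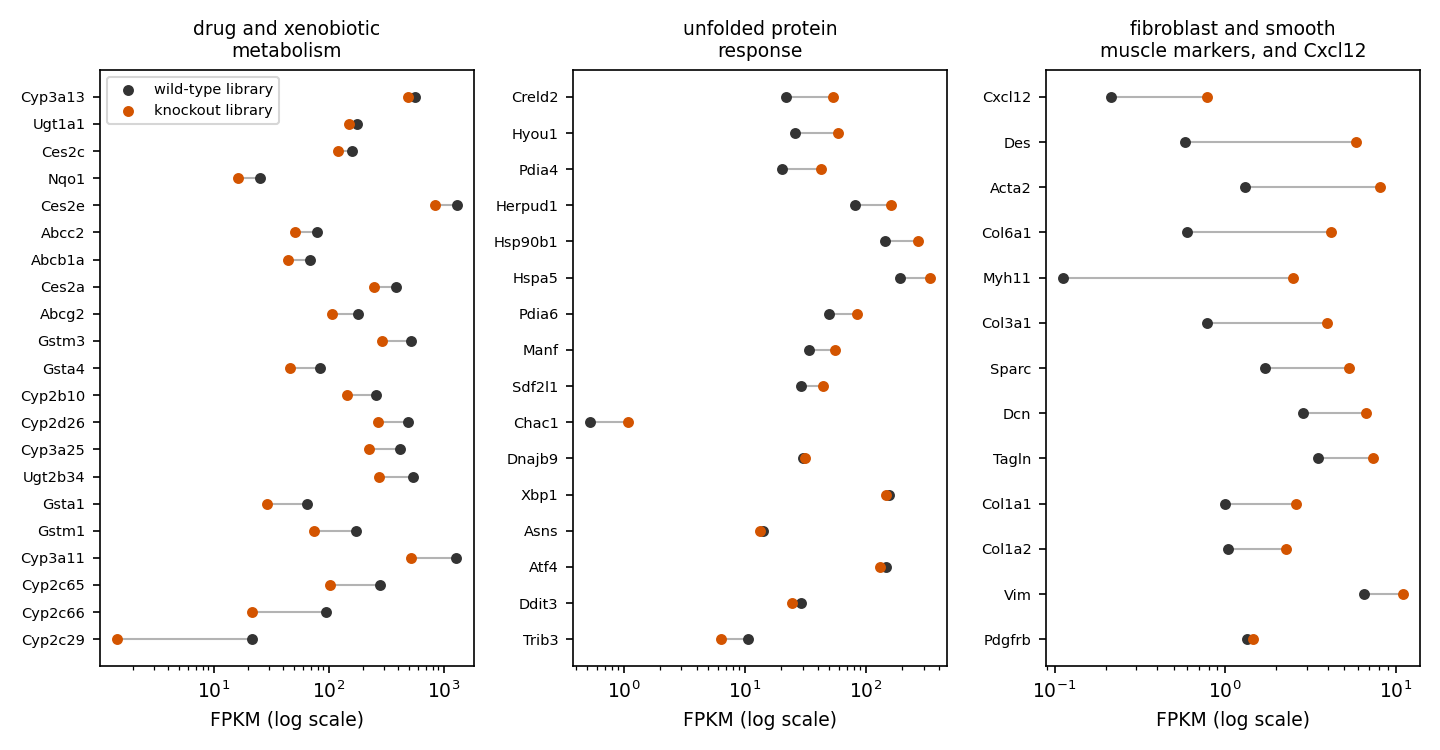
FPKM on a log axis of the measured members of the drug metabolism, unfolded protein response and stromal lists, and of Cxcl12, with the wild-type library in dark grey and the knockout library in orange, 1 value per library. All 21 drug metabolism genes lie lower in the knockout library and all 12 stromal markers higher.

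Stress genes formed a further group. Unfolded protein response genes had a median of 0.63, above every random list, with 11 of 16 above 0 and 3 at least 2-fold. Creld2 was at 21.8 and 53.8 FPKM, Hyou1 at 26.2 and 59.1, Pdia4 at 20.5 and 42.2, and Hspa5, the most abundant, at 192 and 337. The 5 members below 0 were Xbp1, Asns, Atf4, Ddit3 and Trib3, the first 2 of which turned above 0 with values rescaled to equal sums; of these Trib3 (10.8 and 6.42 FPKM) was the lowest. Immediate early and heat shock genes had a median of 0.28 (percentile 99.98, 10 of 17 above 0), with Hsph1 at 6.84 and 19 FPKM, Fosb at 1.52 and 4.04 and Zfp36 at 152 and 184. Of the 7 members below 0, Gadd45a, Hspb1, Ier2, Ier3 and Nr4a1 stayed below 0 with values rescaled to equal sums. Circadian clock genes did not stand apart (median -0.05, percentile 46.4, mean 0.11, so that both signs occurred): besides Per1, Per2 was at 2.28 and 5.28 FPKM, Nfil3 at 27.8 and 14.6 and Dbp at 1.88 and 1.08. Targets of p53 had a median of 0.04 (percentile 81.6), with Pmaip1 at 36.4 and 93.5 FPKM and Fas at 37.3 and 22.

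Transcripts that carry a miR-215 seed site were then examined. Of 10998 measured genes with an annotated 3' UTR, 771 held the heptamer TAGGTCA, which pairs with positions 2 to 8 of miR-215 and of miR-192, in the longest 3' UTR. Their median log2 ratio was -0.01 against -0.05 for genes without it. The difference of 0.05 was at percentile 93.3 among 629 heptamers of the same base composition, whose central 95% ran from -0.01 to 0.07, so the seed-site genes did not stand apart. The heptamer CTGTTAC of miR-194 was in 1265 genes, with a difference of 0.02 at percentile 44.9 among 419 heptamers. None of the 3 annotated 3' UTRs of Cxcl12, of 5188, 2768 and 1487 nt, held TAGGTCA, and each held 0 of the shorter hexamer matches. The list of reported miR-192 and miR-215 targets had a median of 0.11 (percentile 94.2, 16 of 24 above 0), with Dtl at 1.31 and 2.32 FPKM and Pim1, the most abundant, at 49.3 and 35.6.

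Genes around the targeted locus were compared with the rest of the genome. Genes listed as neighbours of Mir215 were lower (median -0.30, percentile 2.22, 10 of 11 below 0, 8 with values rescaled to equal sums, none 2-fold), with Mosc1 at 1.26 and 0.303 FPKM, Mosc2 at 434 and 262 and the manganese exporter gene Slc30a10 at 11 and 7.6. The call was lost under 6 of the 12 alternatives tried, for example with values rescaled to equal sums (median -0.16, percentile 2.71). Among measured genes with a known position, without those whose annotated transcripts are all under 200 nt and so without Mir215 itself, 4 of 83 within 10 Mb of Mir215 were at least 2-fold apart, 4.82% with an exact 95% interval of 1.33% to 11.9%, against 335 of 11256 elsewhere, 2.98%. The 4 genes were 1700016C15Rik, Adck3, Ephx1 and Sccpdh, all lower in the knockout library, and they were named after their values were seen.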

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

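The removal of genes under 200 nt and of the trend with transcript length, the scaling to equal sums on the wild-type scale and the Paneth cell list without alpha-defensins were chosen after the data were seen; the other alternatives were fixed before. No paired analysis was possible because each genotype had 1 library, and for the same reason no replicate could be left out, so the alternatives bear on processing and not on variation between mice. No result changed direction where it had been called: of 417 list values under an alternative, 10 lost a call, 15 gained one and the others kept theirs, and of 162 values of named genes 159 stayed on the same side of 2-fold; the others were Cxcl12 at 1.49 with a pseudocount of 0.1, and Xist and Des at 0.97 and 0.96 with a pseudocount of 5. The 4 alternatives for seed sites left the genes with a site within the range of other heptamers. The numbers of genes past the threshold, 154 higher and 235 lower, became 339 and 361 with a pseudocount of 0.1, 60 and 120 with a pseudocount of 5, 556 and 835 at 1.5-fold, and 49 and 78 at 3-fold, as the size rule itself sets these numbers. Higher genes numbered 259 with both libraries raised to a common sum, which also raised the values against the pseudocount and the filter, 209 with equal sums on the wild-type scale, and 97 with a minimum of 5 FPKM. List members at least 2-fold higher, 24 with the main settings, were 38 with a pseudocount of 0.1, 12 with a pseudocount of 5 and 37 with both libraries raised to a common sum. The list of genes near Mir215 lost its call with both libraries raised to a common sum (-0.17), equal sums on the wild-type scale (-0.16), a minimum of 5 FPKM (-0.30), a mean of at least 1 FPKM (-0.28), the mean of members (-0.29) and the length trend removed (-0.23). With the mean of members the interferon list (0.22), the T cell list (0.15) and the list of PPARA targets and fatty acid oxidation (-0.28) also lost theirs. With the length trend removed the distal intestine list (-0.28) lost its call, the list of IL-17 and IL-22 responses (0.15) gained one, and 2 lists in place of 5 stood apart as lower, the red blood cell list then having fewer than 3 members with a known length. The cause of the lost and gained list calls was not tested. The other gained calls were of the tuft cell, endothelial, chemokine, p53, proximal intestine and reported target lists. Depth limits genes near 1 FPKM, where about 18 fragments in 2 kb give a counting CV of 23.7%, and it leaves the low cytokine genes unresolved. The loss of Mir215 stays unresolved too, in libraries made from polyadenylated RNA and not from small RNA.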

Other observations

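Some of the tests in this part were chosen after the result was seen: those of stromal tissue and of epithelial share for Cxcl12, of the intestinal stretch and the enterocyte share for drug metabolism, of the strain segment for the class I and defensin genes, and of the time of day for the Per genes, whose limits were set with the clock genes in view. The genes in the next paragraph were also picked after their values were seen and were named by no rule fixed before.

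Several further genes were far apart. The metallothionein genes Mt1 and Mt2, which bind zinc and copper, were at 509 and 172 FPKM in the wild-type library and at 155 and 39.8 in the knockout library. Reg1, a secreted regenerating-family protein, was at 2110 and 411 FPKM. Lower values were also seen for Cyp2c55 at 98.4 and 21.6 FPKM, the arylacetamide deacetylase gene Aadac at 377 and 107, the carboxylesterase genes Ces1g at 28.5 and 6.12 and Ces1d at 21.0 and 4.38, Hsd17b13 at 84.6 and 20.3, Ugt2b5 at 32.7 and 7.68 and Adh4 at 55.9 and 11.5. In the higher direction, the mucosal scavenger receptor gene Dmbt1 was at 92.7 and 233 FPKM, Tppp3 at 10.8 and 37.5, and Nlrp9b, an inflammasome sensor of the intestinal epithelium, at 10.5 and 33.6.

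The first pattern is the higher Cxcl12 value in the knockout library, and a lower epithelial share, which raises every cell type outside the epithelium alike, would have moved the stromal list and the list of macrophages, dendritic cells and neutrophils together. Both were higher, but their medians were 0.59 apart, with a lower bootstrap bound of 0.25, against 0.36 at the upper end of random lists. The bootstrap redrew the genes of each list, so its bound does not cover variation between preparations. Counting error stays open, because the lower bound of the fold was 1.39 with the median transcript length but 0.967 with the shortest and 1.76 with the longest. More subepithelial stromal tissue in the knockout preparation is a candidate explanation. The log2 ratio of the Cxcl12 FPKM, 1.87, lay inside the range of the stromal markers, 0.12 to 4.48 with a median of 1.5, and 5 of 12 had a larger ratio. That range is wide enough to hold most increases, so a value inside it tests this explanation only weakly. No stromal marker stood on another list, and the most abundant, Vim, was at 6.56 and 11 FPKM; an effect of the genotype on Cxcl12 itself or on the stroma remains open beside it.

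The lower drug metabolism genes are the second pattern. The trend with transcript length does not account for it, since the median after removal of that trend was -0.75, still below every random list. Another stretch of the small intestine would have moved the proximal and distal lists apart; without the drug metabolism genes their medians differed by 0.16, with a bootstrap 95% interval of -0.31 to 0.44 that leaves this open. A lower share of enterocytes would have lowered the enterocyte markers as much, but the lower bound of their median, -0.28, was above the upper bound of the drug metabolism genes, -0.62. The bootstrap bounds here were likewise drawn over the genes of each list and do not cover variation between preparations. A difference in diet, microbiota, strain or handling between the 2 preparations and an effect of the genotype were not tested and may each contribute to it, as 1 library per genotype keeps them together.

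The class I and alpha-defensin genes among the largest differences are the third pattern. The summed FPKM of 19 alpha-defensin genes differed by 0.16 on the log2 scale (8220 and 9201), and that of 19 class I genes by 0.027 (4751 and 4839). With no read assigned to another copy, the 5 defensin genes 2-fold higher would have moved their sum by only 0.18, the 4 lower by -0.21, and the 3 higher class I genes, where none was 2-fold lower, theirs by 0.14. The sums are therefore no test of reads assigned to other gene copies in the 2 libraries, which stays open. Of the 12 changed genes, 0 lay within 10 Mb of Mir215, and 2 had no known position. This count was set by where the genes lie, for example H2-Bl and H2-Q7 on chromosome 17 and Mir215 on chromosome 1, and not by their values. It shows only that the genes with a known position are outside that window, and it cannot test for a segment of another strain around Mir215. A difference in strain elsewhere was not tested.

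The remaining tests are given as values. The genes with a miR-215 seed site, which release from repression would raise, were at percentile 93.3 among same-composition heptamers, short of the outer 2.5% and with a difference above 0, so that release stayed open. The share of genes at least 2-fold apart near Mir215 had an upper bound of 11.9%, which leaves a strain segment there open as well. Fkbp5, Per1 and Ddit4 are known glucocorticoid targets, as are Sgk1 (217 and 503 FPKM), Pck1 (235 and 574) and Angptl4 (65.1 and 152), and a glucocorticoid response was therefore tested on 14 further measured targets, listed after that pattern was seen and before their own values were looked at. Their median log2 ratio was 0.06, at percentile 88.5, with Tsc22d3 at 77.5 and 159.8 FPKM and Klf9 at 6.58 and 11.6 but Cebpb at 14.1 and 6.56, so that the response may or may not be there. Another time of day at collection would have moved other clock genes beside Per1 and Per2. The largest log2 ratio of FPKM in size among the 10 others measured was -0.93, of Nfil3, short of 2-fold but well apart, and the rhythmic gene Noct, outside that list, was at 10.7 and 45.5 FPKM, so that the time of day stays open.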
